A study of Homo sapiens with 6 samples.

How the data were processed

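Per the labels' protocols, RNA was extracted with Trizol and 1 µg of total RNA per sample was made into libraries with a TruSeq RNA kit for Illumina sequencing. The 6 libraries carry the label HepG2, the name of an established human line derived from a liver tumour, and fall in 2 groups of 3, labelled ABCF1 and NC-1. The authors deposited 2 gene tables with 60612 Ensembl genes each. Gene counts in the second table are whole numbers, deposited without normalization. The first table holds the authors' RPKM, reads scaled to transcript length and library depth, for the same genes and libraries. Per the submitters' processing notes, the tools were CASAVA 1.8, Trimmomatic, FastQC, HISAT2, StringTie and edgeR, with the GRCh38 build. The notes used here give no role for each tool, and the annotation release, the counting settings and any use of strand are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart.

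The deposited counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM normalization, genes kept by edgeR's expression filter, two-sided, Benjamini-Hochberg adjustment over 16545 genes). A gene was called at an adjusted p under 0.05, and a call of 2-fold or more needed a fitted log2 fold change of at least 1 in size. Standard errors were taken as the size of the log2 fold change divided by the square root of its F value. Fold changes are ABCF1 over NC-1 throughout, and values per library are counts scaled to TMM-adjusted library size (CPM). Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The smallest chi-square per degree of freedom between libraries of a group was 11.4 over genes of at least 20 counts, so no library pair agreed within sampling noise.

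Before the data were examined, 45 gene lists with 1125 entries, the test, the alternatives and the rule for named genes were fixed. All list entries matched a gene in the deposited tables. Lists with 5 or more tested members were compared with camera in limma 3.58.1 (preset inter-gene correlation of 0.01, prior count of 2), again with an estimated correlation, and with fry. The rule named ABCF1 and, in each direction, the 10 called genes with the largest fold change and the 5 with the smallest p, given a mean of 2 CPM or more, groups that did not overlap and a gene symbol. XIST and Y-linked genes were left out by that rule. From each list described, it named up to 4 called members with the smallest p, or the 2 members with the highest mean CPM where fewer than 2 were called.

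Other settings chosen beforehand were DESeq2 1.42.0 size factors, upper-quartile factors, library size only, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, limma-trend on log2(RPKM + 1) or log2(RPKM + 0.1), the replicate number as a block, each library left out in turn, and an adjusted p under 0.01. Fold changes on the log2(RPKM + pseudocount) scale understate the change of low genes. After the data were seen, further fits were added because 2 libraries stood apart and because libraries differed by transcript length and GC content. They took as a covariate the side of the first principal component on which a library lay (called the library set below), left those 2 libraries out, or removed each library's smooth trend with transcript length and GC content by a per-gene offset. Length and GC came from the longest transcript of each gene in GENCODE 29 on GRCh38, which holds 58394 of the 60612 genes, 77.0% of them at identical coordinates. Of the tested genes, 98.9% had a value. Because the library set was read from the same counts, p-values of that fit are not those of a planned design. The rule for naming genes was fixed beforehand for the fit without it, which called no gene, and was applied to the library set fit only after that was seen.

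The test was tested on simulated data for ABCF1 against NC-1, with negative binomial counts for 16545 genes, 200 of them changed, in 10 runs. At the spread estimated over all libraries, edgeR recovered 23.1% of genes changed 1.5-fold, 79.9% of those changed 2-fold and 99.4% of those changed 4-fold, and 6.53% of its calls were false. At the smaller spread left after the library set, it recovered 80.7%, 91.8% and 99.7%, with 8.01% false calls. With no gene changed and the set taken from the first principal component of the simulated libraries, at most 10 genes were called in any of 9 runs at the smaller spread. The simulated genes varied independently and shared no trend with length or GC content, unlike those of the real libraries. These runs therefore do not show how many calls of the library set fit were false. A list of 30 genes raised 1.5-fold was called in 10 of 10 runs and no other list was. These list runs used the smaller spread left after the library set. The rise was also larger than the median change of each of the 7 lists called in the real data, so they do not show how often such lists would be found. List members varied independently there too, so these runs could not show false list calls that come from members varying together. A simulated GC trend between the groups with no changed gene gave a median of 9624 calls without the offset and 1.5 with it. That trend was linear in the same GC values that the offset uses, and no length trend was simulated. Whether the offset keeps real differences that follow GC content was not tested. Total counts were 62323034 to 77394510 per library, and for genes of 2 to 6 CPM the median counting error was 6.40% of the value. The median spread between libraries of these genes, as moderated by edgeR, was 21.9%, or 19.6% with the library set. The SD over 3 libraries of a single gene can lie below its counting error, as for TM4SF19 (4.61 ± 0.15 CPM).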

Results

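RNA sequencing compared cells labelled ABCF1 with cells labelled NC-1, with 3 libraries in each group. All 6 libraries are labelled HepG2, the name of a liver tumour line, although transcripts of secreted liver proteins were near 0 in them, as given below. The series concerns the overexpression of ABCF1 in stable HepG2 lines and its design text speaks of forms with lysines replaced by arginines. The sample labels give only the name ABCF1, so which form the libraries carry is not settled by them. Total counts ran from 62323034 to 77394510 per library, and 20356 to 21012 genes had at least 1 count. As the series describes it, the comparison asks which transcripts differ in cells made to overexpress ABCF1. The ABCF1 transcript was lower in the libraries labelled ABCF1, as given next, so overexpression is not shown by these counts.

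ABCF1 encodes a ribosome-associated protein of the ATP-binding cassette family that takes part in translation initiation. Its transcript was lower, not higher, in the libraries labelled ABCF1, at 106 ± 4.05 CPM (SD, n = 3) against 158 ± 3.62 CPM (SD, n = 3) in NC-1. The counts were 6406, 7442 and 7944 in the libraries labelled ABCF1 and 11583, 10098 and 10635 in those labelled NC-1. The deposited RPKM ran from 27.7 to 28.6 against 43.3 to 47.3. The log2 fold change was -0.57 (SE 0.08), and all 3 libraries labelled ABCF1 lay below all 3 labelled NC-1, a separation that 10% of genes show by chance with 3 against 3. The gene had been named before the data were examined, and its unadjusted p in the edgeR test was 1.3e-04. Adjusted over all tested genes, the edgeR p was 0.25 and did not pass, whereas the DESeq2 Wald test gave an adjusted p of 6.1e-08. Over the 23 alternative settings the log2 fold change stayed between -0.68 and -0.55, with adjusted p from 6.1e-08 to 0.87. ABCF1 (ENSG00000204574) lies on chromosome 6 from 30571393 to 30597179 on the plus strand (GRCh38), and the gene that overlaps it, MIR877, took 2 to 4 counts per library. Because this transcript goes against its label, the group is called the libraries labelled ABCF1 here, and every direction below refers to the labels as given.

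**Figure D1:**
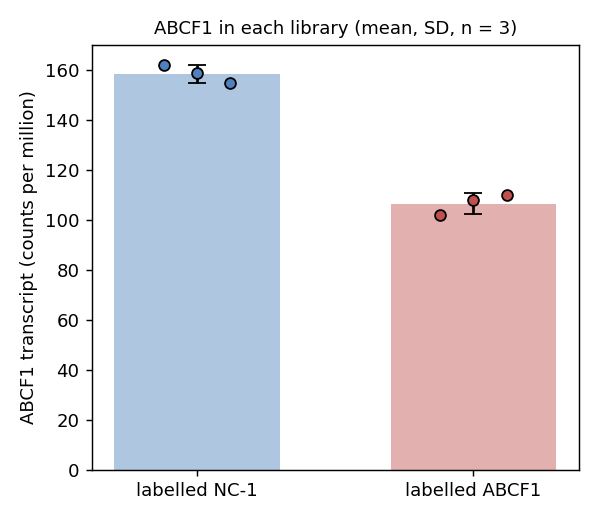
ABCF1 transcript in CPM (vertical axis, from 0) in the 3 libraries labelled NC-1 and the 3 labelled ABCF1; points are libraries, bars the group means and error bars the SD. All libraries labelled ABCF1 lie below all libraries labelled NC-1, with means of 106 and 158.

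No gene was called between the groups by edgeR, with 0 of 16545 genes higher and 0 lower. At an unadjusted p under 0.05 there were 1037 higher and 1413 lower genes, and ABCF1 had the smallest p. Setting ABCF1 replicate 1 and NC-1 replicates 1 and 3 against the other libraries gave 3041 such genes, against 2450 between the labelled groups. The remaining divisions into 3 and 3 gave 128 to 1482. limma-voom and limma-trend on the deposited RPKM also called 0 genes, and the DESeq2 Wald test called 243 higher and 383 lower. The 2 deposited tables gave like differences, with a Spearman correlation across genes, which are not independent replicates, of 0.87 between fold changes from counts and from RPKM, and 0.96 over the 11914 genes with a mean of 1 RPKM or more.

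The libraries differed along transcript length and GC content. ABCF1 replicate 3 and NC-1 replicate 2 lay apart from the other 4 on the first principal component, with scores of 47.2 and 42.0 against -29.3 to -6.96. Relative to the mean of each gene, GC-rich transcripts were higher in each of the 3 libraries labelled ABCF1 (Spearman rho across genes 0.38 to 0.54) and lower in each of the 3 labelled NC-1 (-0.46 to -0.31). Across 11147 genes the fold change between the groups had a rho of 0.69 with GC content and -0.45 with transcript length. No label names a batch.

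**Figure D2:**
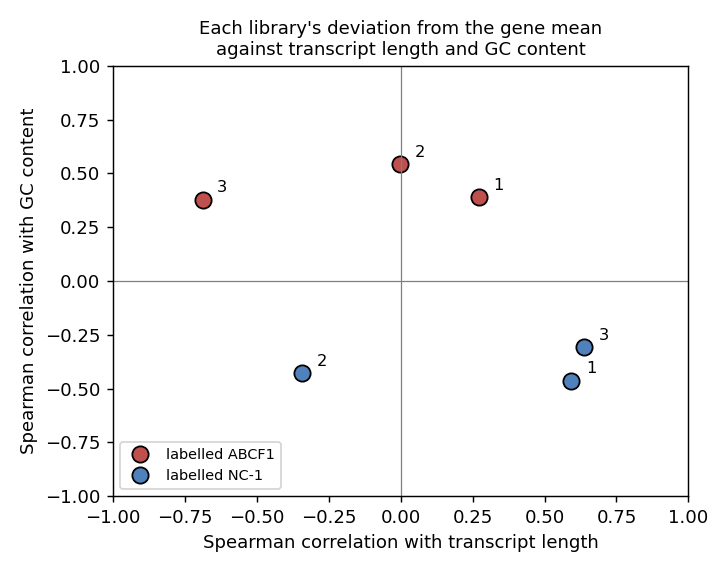
Spearman correlation across genes of each library's deviation from the gene mean with transcript length (horizontal axis) and with GC content (vertical axis), numbered by replicate. Libraries labelled ABCF1 lie above 0 on the GC axis and those labelled NC-1 below it, and ABCF1 replicate 3 (-0.69) and NC-1 replicate 2 (-0.34) have the lowest length correlations.

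Among the 45 gene lists, camera called 7 as higher in the libraries labelled ABCF1 and 0 as lower, while no member of these lists was called on its own over all genes. These lists are read beside the GC and length differences described above, and none was called with an estimated correlation. Cytosolic ribosomal proteins, the structural proteins of the cytosolic ribosome, had a median log2 fold change of 0.33, with 75 of 78 members positive (camera adjusted p = 1.2e-08, adjusted p = 0.96 with an estimated correlation). RPL13A was at 4214 ± 935 CPM against 3343 ± 685 CPM and RPL7A at 3631 ± 605 CPM against 2846 ± 341 CPM (SD, n = 3). Ribosomal protein genes share sequence with many processed pseudogenes, so the split of their reads is uncertain. Glycolysis enzymes had a median of 0.26 with 19 of 22 positive (adjusted p = 2.9e-06, adjusted p = 0.20 with an estimated correlation), and 12 of them passed as higher adjusted over the list alone. For glycolysis, fry's directional test gave an adjusted p of 0.0043, and it called no other list. Its mixed test, which counts members changed in either direction, called 20 lists. With the library set described below as a covariate the directional test called 7 lists and the mixed test 42, and with the length and GC offset added 1 and 35. GAPDH was at 12062 ± 1323 CPM against 9267 ± 233 CPM, and PGK1 at 5218 ± 61.97 CPM against 4263 ± 47.9 CPM.

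Immediate early genes, which respond within minutes to growth factors and stress, had a median of 0.22 with 22 of 25 positive (camera adjusted p = 1.2e-05, adjusted p = 0.46 with an estimated correlation). JUNB was at 416 ± 33.5 CPM against 341 ± 24.9 CPM, and FOSL2 at 320 ± 57.2 CPM against 319 ± 65.3 CPM. Respiratory chain genes encoded in the mitochondrial genome had a median of 0.50, and all 13 were positive (adjusted p = 0.0015, adjusted p = 0.89 with an estimated correlation). NC-1 replicate 3 had the lowest share of mitochondrial counts, 1.48% against 2.24% to 2.52% in the other libraries, and without it the list median was 0.20. MT-CO1 was at 6220 ± 135 CPM against 5311 ± 1057 CPM and MT-ND4 at 3157 ± 236 CPM against 2359 ± 880 CPM. Nuclear-encoded respiratory chain genes had a median of 0.21 with 39 of 42 positive (adjusted p = 0.0015, adjusted p = 0.96 with an estimated correlation). ATP5F1B was at 1532 ± 69.8 CPM against 1299 ± 80.5 CPM and SDHA at 632 ± 17.7 CPM against 562 ± 16.5 CPM. This call was lost without ABCF1 replicate 3 (adjusted p = 0.33), NC-1 replicate 1 (0.10) or NC-1 replicate 3 (0.12).

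Autophagy and lysosome genes had a median of 0.14 with 19 of 27 positive (camera adjusted p = 0.0032, adjusted p = 0.46 with an estimated correlation), and 7 passed as higher adjusted over the list alone. LAMP1, a lysosomal membrane protein, was at 413 ± 8.84 CPM against 326 ± 7.44 CPM, and SQSTM1, an autophagy receptor, at 418 ± 8.66 CPM against 381 ± 12.96 CPM. Lipid droplet and lipolysis genes had a median of 0.20 with 11 of 15 positive (adjusted p = 0.024, adjusted p = 0.46 with an estimated correlation). PLIN3, a lipid droplet coat protein, was at 318 ± 11.5 CPM against 259 ± 12.3 CPM and HILPDA at 146 ± 4.16 CPM against 127 ± 11.8 CPM. This call was lost without ABCF1 replicate 1 (adjusted p = 0.066), ABCF1 replicate 2 (0.060), NC-1 replicate 1 (0.061) or NC-1 replicate 3 (0.14), and with the library set as a covariate (0.082). Interferon-stimulated genes (median 0.12, 30 tested, adjusted p = 0.87), integrated stress response targets of ATF4 (0.08, 29 tested, 0.42), translation initiation factors (0.04, 35 tested, 0.71, but 0.022 with the length and GC offset, where an estimated correlation gave 0.73) and cholesterol synthesis and uptake genes (0.10, 25 tested, 0.98) were not called by camera. Of the ABCF and related transporter list, 3 of 10 members (ABCF1, ABCD3 and ABCE1) were lower adjusted over the list alone, and the list was not called (adjusted p = 0.34).

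**Figure D3:**
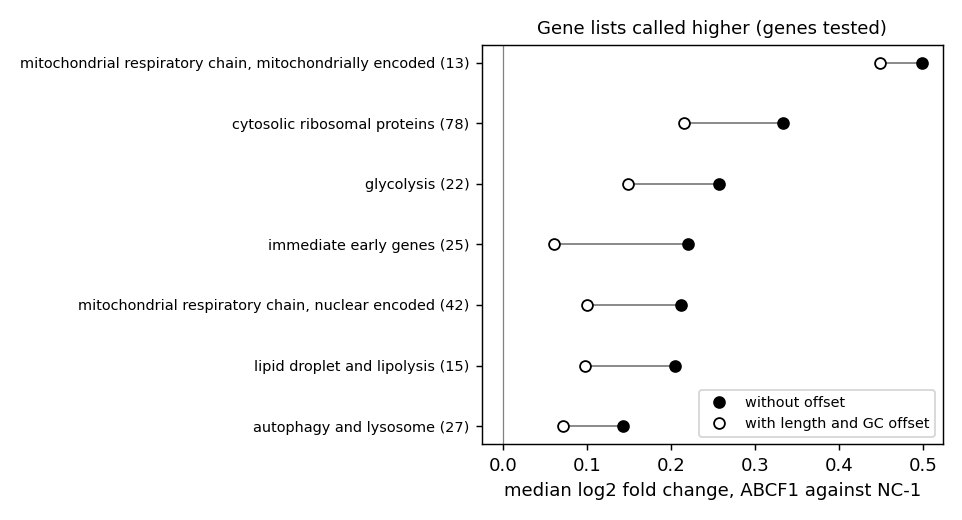
Median log2 fold change of the libraries labelled ABCF1 against NC-1 (horizontal axis) in the 7 lists called higher, with the number of genes tested in parentheses; filled points are without and open points with the offset for transcript length and GC content. Each median is lower with the offset, from 0.33 to 0.21 for ribosomal proteins and from 0.22 to 0.06 for immediate early genes.

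With the library set as a covariate, an alternative added after the data were seen, edgeR called 2129 higher and 2064 lower genes, of which 25 and 35 changed 2-fold or more. The naming rule asked for a mean of 2 CPM or more, groups that did not overlap and a gene symbol. Among genes that met it, the 5 with the smallest p in each direction are given first. RPLP0, a ribosomal protein, and the glycolysis enzymes ALDOA and TPI1 rose by log2 fold changes of 0.43 (SE 0.03), 0.36 (SE 0.03) and 0.38 (SE 0.04). BSG, a membrane glycoprotein that accompanies lactate transporters, rose by 0.38 (SE 0.04) and FOLR1, a folate receptor, by 0.41 (SE 0.04). EIF1AX, a translation initiation factor, had a log2 fold change of -0.49 (SE 0.04), GALNT1 of -0.50 (SE 0.05), CENPF, a kinetochore protein, of -0.54 (SE 0.05), FAM102B of -0.63 (SE 0.06) and ABCF1 of -0.57 (SE 0.05), at adjusted p of 9.1e-04 or less in this edgeR fit for all 10 genes named so far by p. The higher genes had short GC-rich transcripts (median 2469.5 nucleotides and 57.9% GC) and the lower genes long AT-rich ones (5361 nucleotides and 40.5% GC), against 3175 nucleotides and 49.2% over all tested genes.

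The largest fold changes in that fit, among genes that met the naming rule, were in genes of low abundance. Higher were BHLHB9, RPL36A-HNRNPH2, MYEOV, AQP1, CCDC159, FOSB, ACVRL1, CIB2, TM4SF19 and NRTN, with log2 fold changes from 0.76 to 1.63. MYEOV rose from 2.96 ± 0.54 CPM to 5.67 ± 0.70 CPM (SD, n = 3), FOSB, an AP-1 transcription factor, from 2.81 ± 0.71 CPM to 4.86 ± 0.69 CPM, and ACVRL1, a receptor of the TGF-beta family, from 2.49 ± 0.52 CPM to 4.28 ± 0.87 CPM. Lower were ARMCX5-GPRASP2, PCDHAC2, CPT1B, DUS4L-BCAP29, FOXP2, ZNF430, ZNF518A, PSD3, BIVM and N4BP2, with log2 fold changes from -2.62 to -0.78. FOXP2, a forkhead transcription factor, fell from 8.97 ± 1.06 CPM to 3.87 ± 2.25 CPM and CPT1B, a muscle-type carnitine palmitoyltransferase, from 3.28 ± 1.70 CPM to 1.13 ± 0.38 CPM. ARMCX5-GPRASP2 overlaps BHLHB9, which went the other way, and RPL36A-HNRNPH2 and DUS4L-BCAP29 are readthrough genes that overlap their parts. PCDHAC2, CPT1B, BIVM, CCDC159, CIB2, TM4SF19, AQP1 and FOSB also overlap other protein-coding genes, so the reads assigned to these genes are uncertain. With the length and GC offset added, 2 of the 10 higher genes (MYEOV and FOSB) and 4 of the 10 lower genes (PCDHAC2, CPT1B, ZNF430 and BIVM) were still called by edgeR. The other 8 higher genes had adjusted p from 0.0502 to 0.20 and 4 lower genes from 0.051 to 0.18, and 2 readthrough genes had no length or GC value. These lost calls do not show that length and GC made the differences. The 8 higher genes kept 65.6% to 112% of their fold change and the 4 lower genes 56.6% to 77.03%, and all 12 stayed over 2 SE from 0. These 12 had been picked for large fold changes called in the same counts, so that distance from 0 is not independent evidence. BHLHB9 went from 1.63 (SE 0.45) to 1.83 (SE 0.46), ACVRL1 from 0.79 (SE 0.20) to 0.66 (SE 0.20), NRTN from 0.76 (SE 0.22) to 0.50 (SE 0.20), FOXP2 from -1.39 (SE 0.28) to -1.07 (SE 0.27) and N4BP2 from -0.78 (SE 0.14) to -0.44 (SE 0.14). With 915 genes called in place of 4193, the largest p that was called went from 0.013 to 0.0028. AQP1, CCDC159, CIB2, NRTN and ZNF518A, with smaller fold changes, had p above the former limit too, and the other 7 genes had p between the 2 limits. In the fit without the library set, leaving out NC-1 replicate 2 moved BHLHB9 from 1.20 to 0.67 and AQP1 from 0.69 to 0.31, leaving out NC-1 replicate 3 moved AQP1 to 1.04, and leaving out ABCF1 replicate 3 moved FOXP2 from -1.21 to -0.80.

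The same fit called 62 of 78 ribosomal proteins higher and 0 lower, among them RPS10 (log2 fold change 0.46, SE 0.04) and RPSA (0.40, SE 0.04). It called 17 of 22 glycolysis enzymes higher and 1 lower, 25 of 42 nuclear respiratory chain genes higher and 2 lower, including NDUFA13 and NDUFS7, and 14 of 25 immediate early genes higher and 1 lower, including FOSL1 (0.55, SE 0.09), IER3 and NR4A1. Among autophagy and lysosome genes 14 of 27 were higher and 1 lower, and CTSD, a lysosomal protease, had a log2 fold change of 0.35 (SE 0.04), ATG9A of 0.35 (SE 0.05) and ATP6V0D1 of 0.35 (SE 0.05). Translation initiation factors went both ways, with 13 of 35 higher (EIF6 and EIF3K) and 8 lower (EIF1AX and EIF3A). Of 35 mitosis genes 13 were lower, including ASPM, KIF11 and TOP2A, and 6 higher. Of 30 interferon-stimulated genes 5 were higher, including ISG15 (0.37, SE 0.04), IFITM3, ISG20 and BST2, and 5 were lower. Among 25 cholesterol genes 7 were higher, including FDPS, and 5 lower, including HMGCS1 (-0.33, SE 0.05), STARD4 and IDI1. In the ABCF and related list ABCF1, ABCD3 (-0.46, SE 0.07) and ABCE1 (-0.45, SE 0.07) were lower and ABCG1 higher. None of these lists was called with an estimated correlation in this fit, where the smallest adjusted p was 0.58. In the fit without the library set, leaving out ABCF1 replicate 3 made the fold changes of RPL13A, RPL7A, RPS10, RPSA, IER3, ISG15, ISG20, BST2, NDUFA13, NDUFS7, FDPS, ASPM, TOP2A, EIF3A and EIF3K smaller by over 1.5 times, for example NDUFA13 to 0.08 and BST2 to 0.05.

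Adding the length and GC offset to the library set left 597 higher and 318 lower genes, of which 629 were also called without the offset and 627 in the same direction. PGK1 (log2 fold change 0.45, edgeR adjusted p = 1.0e-05), RPLP0 (0.34, edgeR adjusted p = 9.8e-05) and ABCF1 (-0.66, edgeR adjusted p = 9.8e-05) passed. All 10 genes named by p were still called, but 8 of them shrank by over 1.5 times, TPI1 to 0.16, BSG to 0.17, FOLR1 to 0.18, ALDOA to 0.22, EIF1AX to -0.21, GALNT1 to -0.25, CENPF to -0.27 and FAM102B to -0.33. Of the 40 members named from the 10 lists in the library set fit, 15 were still called and 25 were not. The fold changes of all 25 were smaller by over 1.5 times, and 14 stayed over 2 SE from 0. These members had been picked by p in the same counts. The calls of ABCD3 (from -0.46, SE 0.07, to -0.21, SE 0.06, edgeR adjusted p = 0.060), ABCE1 (from -0.45, SE 0.07, to -0.23, SE 0.06, edgeR adjusted p = 0.067) and ABCG1 (from 0.29, SE 0.07, to 0.18, SE 0.06, edgeR adjusted p = 0.12) were lost, as were those of all 4 immediate early genes and all 4 cholesterol genes named. Ribosomal proteins had 45 of 78 members higher and 0 lower, and glycolysis 11 of 22 higher and 1 lower. Nuclear respiratory chain genes had 11 of 42 higher and 0 lower, and autophagy and lysosome genes 5 of 27 higher and 1 lower. Immediate early genes had 2 of 25 higher and 0 lower, and cholesterol genes 1 of 25 higher and 1 lower. Translation initiation factors had 6 of 35 higher and 1 lower, with 27 of 35 fold changes positive. Mitosis genes had 2 higher and 2 lower and interferon-stimulated genes 2 higher and 0 lower. Without ABCF1 replicate 3 and NC-1 replicate 2, the other 4 libraries gave 950 higher and 853 lower genes. Of the 1799 genes called there and measured in the pair left out, 1764 (98.1%) differed in the same direction in that pair, which shares the group difference in GC content. With the length and GC offset 193 genes were called among the 4 libraries and 183 (94.8%) had the same direction in the pair left out.

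Transcripts of secreted liver proteins were near 0 in both groups. Of 32 such genes 3 had a mean of 1 RPKM or more, the highest being VTN at 23.2 ± 0.92 RPKM in the libraries labelled ABCF1 and 20.3 ± 0.99 RPKM in NC-1 (SD, n = 3). ALB, which encodes serum albumin, had at most 0.18 RPKM in any library, AFP at most 0.16, SERPINA1 at most 0.10, TTR at most 0.13, APOA1 at most 0.04 and APOB at most 0.02. Of 21 apolipoprotein and lipoprotein secretion genes 3 reached a mean of 1 RPKM, and of 25 drug-metabolising enzymes 4 did. Of 20 liver transcription factors 8 reached it, HNF4A at 14.99 to 31.2 RPKM among them, while FOXA2 was at 0 in every library. Of 18 fetal liver and liver tumour markers 10 reached a mean of 1 RPKM. Of 22 bile acid metabolism and transport genes 8 did. H19, a fetal transcript, had a mean of 117 RPKM, KRT7, a keratin listed among cholangiocyte markers, 141 RPKM, and VIM, an intermediate filament protein, 797 RPKM. CGA, the alpha subunit of the glycoprotein hormones, had a mean of 2277 RPKM and ranked 15 among all genes, and FOLR1 had 2090 RPKM and ranked 18. KRT17, a basal keratin, had 431 RPKM and CDKN2A, a cell cycle inhibitor, 191 RPKM. The lists were fixed beforehand, and the genes named in this paragraph, in them or not, were chosen after their values were seen.

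**Figure D4:**
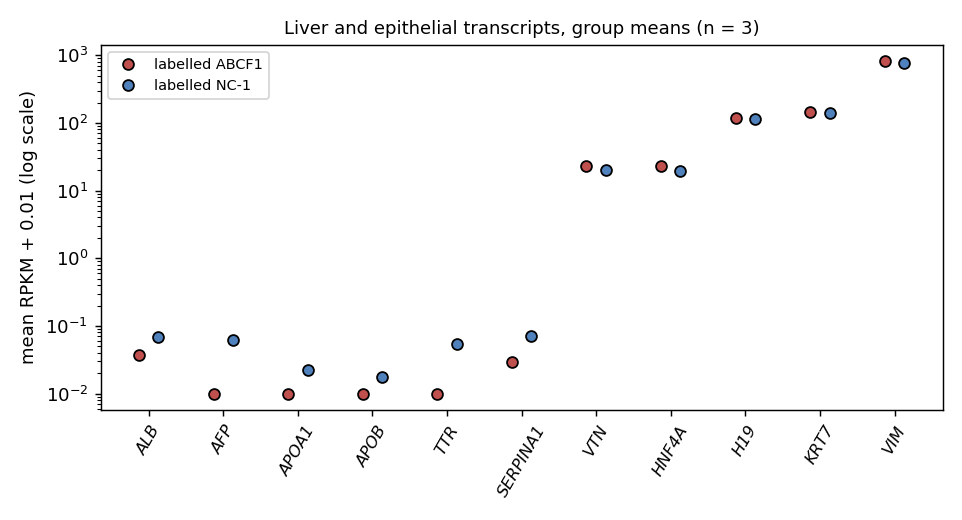
Mean RPKM plus 0.01 on a log axis (vertical) of 11 transcripts (horizontal) in the libraries labelled ABCF1 and NC-1, 3 libraries per point. ALB, AFP, APOA1, APOB, TTR and SERPINA1 lie below 0.1 in both groups, and VTN, HNF4A, H19, KRT7 and VIM lie above 10.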

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

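The fits with the library set, with 4 libraries and with the length and GC offset were chosen after the data were seen, and the other settings were planned. The count of 0 genes by edgeR stayed at 0 to 0 in each direction, and at 2-fold or more, with each library left out. It was also 0 with other scalings, filters, limma-voom, limma-trend, the offset alone and an adjusted p under 0.01. DESeq2 called 243 higher and 383 lower (2 and 1 at 2-fold or more), with 5456 adjusted p-values given as NA. The library set as covariate gave 2129 and 2064 (25 and 35), the 4 libraries 950 and 853 (18 and 22), and the library set with the offset 597 and 318 (10 and 13). The smaller spread between libraries under the library set (median biological coefficient of variation 9.70% against 16.3%) shows why more genes passed. For ABCF1 these 4 settings gave log2 fold changes of -0.56, -0.57, -0.59 and -0.66 past the threshold, and -0.59 to -0.55 with each library left out. Called lists numbered 5 to 8 with each library left out, 0 with an estimated correlation (also with the library set, the offset or both), 1 (glycolysis) with fry's directional test, 9 with the offset (adding hypoxia response and translation initiation factors) and 9 with the filter of 1 CPM. Translation initiation factors also passed with the offset and library set (adjusted p = 0.014, but 0.59 with an estimated correlation). The number of lists called lower stayed at 0. RPKM against counts moved to 0.94 with a pseudocount of 0.1. The replicate numbers did not pair the libraries (correlations of deviations of 0.11, -0.11 and -0.15 for numbers 1, 2 and 3), and with the replicate block 0 genes were higher and 0 lower, 7 lists were called and ABCF1 was at -0.57. FOSL2, near 0, turned to -0.094 with library size only, -0.085, -0.086 and -0.085 with limma-trend, -0.017 in 4 libraries, -0.020, -0.019 and -0.019 with the 3 offset fits, and lay between -0.16 and 0.15 with each library left out. SQSTM1 turned to -0.032, -0.031 and -0.031 and BST2 to -0.058, -0.058 and -0.058 with the 3 offset fits. The cause was not tested for FOSL2, and for the others the offset itself removes a trend with length and GC. Of the remaining values for single genes and lists, 1510 kept direction and side of the threshold, 171 passed only in the alternative and 23 no longer passed. For genes of 2 to 6 CPM the median counting error (6.40%) was below the median spread between libraries (21.9%), while single low genes lay closer to it.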

Other observations

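The tests of the length and GC trend on ABCF1, of exchanged labels and of liver gene models were chosen after the result was seen. The splits of the libraries, the overlapping gene, the matched lists and the mitochondrial library were set before their results. The gene lists given matched lists were taken from those that camera had called. With 3 against 3 there are 10 splits of the 6 libraries, so no share under 0.05 can be reached. edgeR called 0 genes in the real split and at most 5 in another, so all 10 splits gave as many. DESeq2 called 626 in the real split and 898 in the highest other, and 2 of the 10 splits gave as many. That other split puts ABCF1 replicate 3 and NC-1 replicate 2 on 1 side, but so do 3 more, where DESeq2 called 24, 10 and 9, so the count does not follow from that pair alone. Camera called 7 lists in the real split and 8 in the highest other, and 3 splits gave 7 or more. Of the 6 splits that part both library sets evenly, 1, the real one, gave 4193 genes and the highest other gave 3, where 6 splits are too few for a share under 0.05.

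The lower ABCF1 transcript in the libraries labelled ABCF1 goes against the series title. The tables argue against the length and GC trend as its cause, since the log2 fold change moved from -0.57 to -0.66 (SE 0.07) with the offset. Counting to the overlapping MIR877 is excluded, since the summed counts still differed by -0.57. An exchange of the 2 group labels stays open, because a log2 fold change of -0.57 is under the 2-fold that was set, once this value was known, as the mark of overexpression in the libraries labelled NC-1. A transgene whose sequence is not counted at this gene, together with a lower transcript of the cell's own gene, may also give this, and it was not tested.

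Of the 7 lists higher in the libraries labelled ABCF1, 6 were set against GC content and length; the mitochondrially encoded list moved little with the offset (0.50 to 0.45). Against 10000 lists matched on abundance, length and GC, the medians lay at the 100th percentile for ribosomal proteins, 99.88 for nuclear respiratory chain, 98.44 for glycolysis, 98.39 for immediate early genes and 97.67 for lipid droplet genes. The matched medians were themselves above 0 (0.17 for ribosomal proteins). Genes of the matched lists were drawn singly, without the shared variation of real list members, so the matched medians may spread too little. The list medians were thus above those of singly drawn genes of like abundance, length and GC. Whether these properties are their whole cause is not decided by the percentiles. The lists had been picked because camera called them higher in the same counts, and the percentiles were not adjusted for that choice. Such a choice favours high percentiles, so those of 97.67 to 98.44 are weak evidence. For autophagy and lysosome genes the percentile was 90.34, so these properties could account for that list. With the length and GC offset camera still called it (adjusted p = 0.022, but 0.60 with an estimated correlation). For mitochondrially encoded genes the median was 0.20 without NC-1 replicate 3, so that library may carry most of it. The group difference that the design names, overexpression of ABCF1, stays open and untested as a source of these differences, and the ABCF1 transcript itself was lower.

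Transcripts of most secreted liver proteins, apolipoproteins and drug-metabolising enzymes were near 0 in a line labelled HepG2. Among fetal liver and liver tumour markers 10 of 18 had a mean of 1 RPKM or more and 8 had less. AFP and GPC3, picked after their values were seen, had means of 0.03 and 0.004 RPKM. Whether gene models that receive no reads had a part is not settled by the counts. For 25 of 32 secreted liver protein genes a read was found in some library, so those models could take up reads. Only 10 reached 20 counts in any library, a bound set once these values were known. A gene with little expression also stays below that bound, so the bound cannot tell these cases apart. Of 25 drug-metabolising genes 12 had any count. Cells other than the label names could also give these low levels, and no cell line profile was used here to test it.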
